A study of Mus musculus with 6 samples.

How the data were processed

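RNA of 6 whole tumours, 3 p63-intact and 3 p63-excised, was hybridised to Illumina bead arrays, per the labels' protocols. A table named non-normalized gives, per the file headers, a signal intensity and a detection p-value for each of 45281 probes on each array. In these deposited intensities each array has the same mean, 131.42, so some scaling had been done before deposit. The detection p-values move in steps of 1 in 936, as a share of negative control probes would. A value table deposited by the authors holds log2 intensities with the same sorted values on each array, as quantile normalization gives, and a median of 6.19 on each array; the method is not given in the sources used here. The submitters' processing notes name R 2.12.0. The authors also deposited a table of 1 comparison with, per the file headers, a log2 change, a signed fold change, a mean log2 level, a t score, an unadjusted p-value and a log-odds score for each gene name. That table lists 16381 entries with p up to 0.462, so genes with a larger p are not analysed here. How its values were normalized, and how probes were joined into genes, is not given in the sources used here.

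From the intensities, normalized log2 values were made with limma's neqc (background from negative controls inferred through the detection p, offset 16, quantile normalization). A probe was tested if its detection p was under 0.05 on at least 3 arrays, which 13727 probes met. The groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment, and the median standard error of a log2 change over tested probes was 0.20. All 6 columns of each value table were used. R 4.3.3 and limma 3.58.1 were used for fits, and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 for gene names. The probe test was tested on simulated data, where it made 9 false calls among 13727 probes beside the shares recovered that the results give. The list test was tested on simulated data as well, and found 50 of 50 shifted lists and called 4 of 50 unshifted ones at an unadjusted p under 0.05. Both simulations drew independent normal values, without differences in array quality, members that vary together or the cut at a p of 0.462. They do not measure recovery or false calls under those conditions.

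The files do not pair probes with genes, so named genes and gene lists rest on the authors' deposited table alone, and no value per array can be given for them. Many settings of background correction and offset were tried to recompute the authors' values from the probes and so pair them with genes; none did, and no such pairing is used. Whether the arrays of both groups stood apart for a named gene, which the rule for named genes had asked, could not be checked. Names were brought to current symbols with a RefSeq gene table of mouse assembly GRCm38.p6: 8764 matched directly, 3091 through an older symbol, and 4526 were kept as given. The array's genome build is not given in the sources used here, so no coordinates are printed. The unadjusted p-values of the authors' deposited table were adjusted by the Benjamini-Hochberg method over 45281 tests, an upper bound. This bound was chosen after call counts at 4 numbers of tests had been seen, and it is the most conservative of them.

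The design, the gene lists and the rule for named genes were set before the data were examined. The rule takes Trp63 and Fgfr2, the 10 highest rises and the 10 deepest falls past the threshold, passing over clone-named transcripts, and up to 4 members of each list with the smallest p. That the rule be applied to current rather than deposited symbols was decided after both readings had been seen; it brings in Mir205hg, Rab26os, Mir17hg, Pisd-ps3 and Mab21l4. By deposited names the falls would have gone on to St6galnac2, Nrbp2, Hnrnpdl and Slc38a2, and the rises would have held Prl2c4. Of 30 gene lists, 29 with at least 5 listed members were tested with limma's cameraPR on the t scores of the authors' deposited table, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. This took the place of camera on probes, which had been planned on the assumption that probes would carry names. Because only entries with p up to 0.462 are listed, a list is compared with other listed entries, not with the whole array. A list count adjusted over the list alone takes each member of the list as a test, listed or not. Alternatives for probes were other background corrections and normalizations, other filters on dim probes, array weights, another variance model, the replicate number as a block and leaving out each array. For lists, other correlations, a rank version, a filter on dim entries and unlisted members set to a t of 0 were added after the data had been seen. Some items that the rule for named genes takes are not reported here.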

Results

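Gene expression was measured in mouse cutaneous squamous cell carcinomas on Illumina bead arrays, on which biotin-labelled cRNA from whole-tumour RNA binds probes for single transcripts. The tumours were induced with the carcinogen DMBA in mice heterozygous for p53, with loxP-flanked alleles of p63 and a Cre recombinase that is expressed from the keratin 14 promoter and activated by tamoxifen. Cells of a primary tumour were transplanted into immunodeficient Nude mice, where tumours grew for 13 days before 5 daily doses of tamoxifen or vehicle. Tumours were harvested 1 to 3 days after the last dose. Tamoxifen-treated tumours form the p63-excised group (3 arrays) and vehicle-treated tumours the p63-intact group (3 arrays), so the drug and the excision always go together. The labels number the tumours but do not say that they grew in separate mice, so p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision. The comparison addresses which genes depend on p63, the transcription factor that maintains squamous epithelium, and what happens to the gene of the growth factor receptor FGFR2, whose signalling the study's title names.

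Of 45281 probes, 16096, 13757 and 15504 were detected above background on p63-intact arrays 1, 2 and 3, and 13214, 11964 and 14520 on p63-excised arrays 1, 2 and 3. The group means were 15119 ± 1216 (SD, n = 3) and 13233 ± 1278 (SD, n = 3). An exact two-sided permutation test gave p = 0.2, and since 3 against 3 arrays cannot go below 0.1, it could not have shown a difference at 0.05. Array p63-excised 2 had the highest median signal, 106.1 against 74.7 to 89.4 on the other arrays, and the fewest detected probes. Correlations between pairs of arrays over tested probes ran from 0.898 to 0.981, and no pair of arrays held identical values. The first principal component held 48.3% of the variance and separated the groups, and the second held 24.8%. Within each group the first component also ordered the arrays by their number of detected probes. It therefore cannot be read as the group difference alone.

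**Figure D1:**
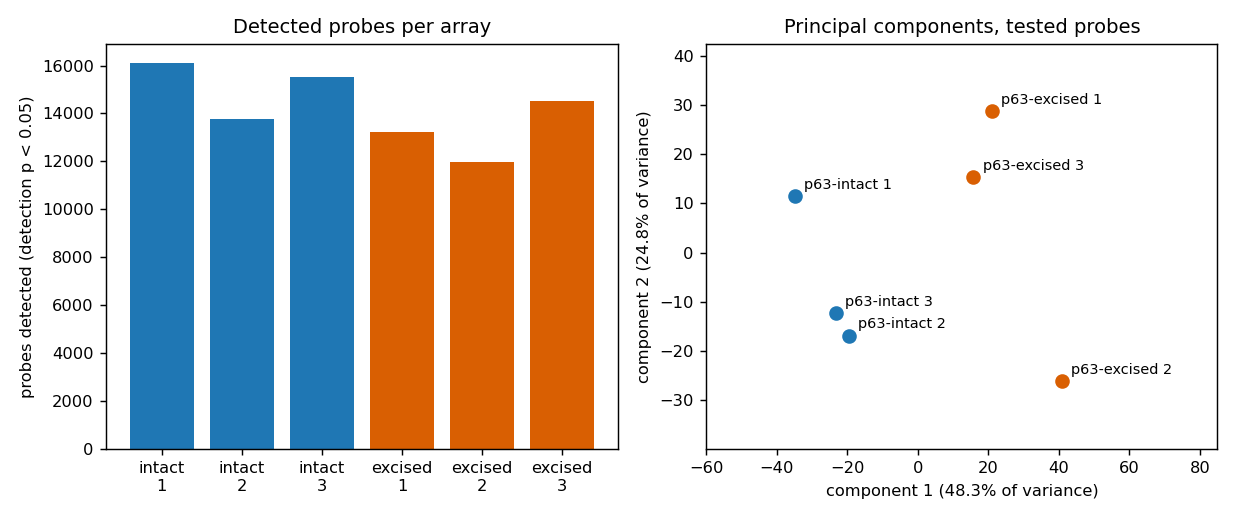
Left, probes detected at a detection p under 0.05 on each array, with p63-intact arrays in blue and p63-excised arrays in orange; right, the first and second principal components of the normalized log2 intensities of 13727 tested probes, 1 point per array. The 3 p63-intact arrays lie at -34.9 to -19.6 on component 1 and the 3 p63-excised arrays at 15.8 to 40.9.

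Between p63-excised and p63-intact tumours, 604 of 13727 tested probes passed a limma test with Benjamini-Hochberg adjustment at 0.05, 319 higher and 285 lower in the excised tumours. At least 2-fold changes made up 176 of the rises and 170 of the falls. Probe ILMN_1221157 rose from 5.35 ± 0.65 (SD, n = 3) to 9.63 ± 0.24 (SD, n = 3) in log2 intensity. Probe ILMN_2960700 fell from 9.26 ± 1.09 (SD, n = 3) to 5.10 ± 0.50 (SD, n = 3), and it was detected on 2 of 3 excised arrays. The limma log2 changes were 4.28 ± 0.30 (SE, adjusted p = 0.000191) and -4.16 ± 0.46 (SE, adjusted p = 0.00152). Probes are given by identifier because the files do not pair them with gene names. In simulated arrays of 13727 probes with 200 changed, the same test recovered 73% of 2-fold and 99% of 4-fold changes. The simulated noise was independent and normal, without differences in array quality, so these shares may be too high for the real arrays. Scaling the arrays to a common median in place of quantile normalization left 50 probes, 14 higher and 36 lower, and moved the median log2 change of tested probes from -0.03 to -0.22. Under other settings, 203 probes passed with no filter on dim probes, 298 without background correction, 396 with normexp at an offset of 50, 380 in the authors' value table and 963 with array weights. Leaving out p63-intact array 1, 2 or 3 gave 301, 224 or 186 probes, and leaving out p63-excised array 1 or 3 gave 328 or 233. Without p63-excised array 2 there were 631. With the replicate number as a block 1324 probes passed, but whether equal numbers pair the tumours is not known.

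Named genes come from the authors' deposited table of changes, which lists 16381 entries with a p up to 0.462. Fgfr2, which encodes a receptor tyrosine kinase for fibroblast growth factors, fell by 1.00 on the log2 scale in the authors' deposited table (t = -8.91, Benjamini-Hochberg adjusted p = 0.0281 with 45281 tests assumed). Trp63, the excised gene, had a log2 change of -0.25 in the authors' deposited table (t = -2.22, p = 0.0639, adjusted p = 0.751) and did not pass. Which part of the Trp63 transcript its probe reads, inside or outside the excised exons, is not given in the sources used here, so this value does not check the group labels. The adjustment uses every probe on the array as an upper bound on the number of tests, because the table lists only part of them.

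In all, 190 entries of the authors' deposited table passed that adjustment, 108 higher and 82 lower in the p63-excised tumours. At least 2-fold changes made up 54 of the rises and 37 of the falls in the authors' deposited table. The highest rises in the authors' deposited table were those of the simple epithelial keratins Krt8 (log2 change 4.04, adjusted p = 0.00953) and Krt19 (3.84, adjusted p = 0.0072). Krt18, the filament partner of Krt8, rose by 2.44 in log2 in the authors' deposited table (adjusted p = 0.0496), and Krt15, a keratin of basal and hair follicle cells, by 2.76 (adjusted p = 0.00833). Akr1c18, a steroid-metabolising aldo-keto reductase, rose by 3.47 in log2 in the authors' deposited table (adjusted p = 0.0172). The prolactin-family genes Prl2c3 and Prl2c2 had log2 changes of 3.24 and 2.99 in the authors' deposited table (adjusted p = 0.0072 and 0.0151), but they are near-identical copies whose probes may not tell them apart. Further rises in log2 in the authors' deposited table were those of Mab21l4 (2.48), the tight junction gene Cldn3 (2.16) and the kallikrein peptidase gene Klk10 (2.15).

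Zxda, a zinc finger gene, Rhbdl2, a rhomboid protease gene, and Prf1, the gene of the lymphocyte protein perforin, fell, with log2 changes of -3.82, -3.70 and -3.36 in the authors' deposited table (adjusted p = 0.0325, 0.0487 and 0.042). Among unnamed probes, 14 fell by over 3 in log2 and deviated together across arrays (mean correlation 0.791), and whether they include the probes of Zxda, Rhbdl2 and Prf1 is not known. Chka, encoding choline kinase alpha, fell by 2.47, and Flrt3, encoding a membrane protein that binds FGF receptors, fell by 1.88 in the authors' deposited table (adjusted p = 0.0325 and 0.0162). The microRNA host transcripts Mir205hg and Mir17hg fell by 2.07 and 1.57 in the authors' deposited table (adjusted p = 0.0106 and 0.00837). Ddx3y, a Y-linked RNA helicase gene, fell by 1.79 in the authors' deposited table (adjusted p = 0.0259), while the Y-linked genes Kdm5d and Usp9y had log2 changes of -0.07 and 0.12 at mean log2 levels of 5.07 and 4.80, near the lowest listed level of 4.62, where a fall could hardly be seen. The noncoding entries Rab26os and Pisd-ps3 had log2 changes of -1.68 and -1.41 in the authors' deposited table (adjusted p = 0.00833 and 0.0375), and Pisd-ps3 is a pseudogene whose probe may read its parent gene. With 16381 listed entries taken as all tests, 486 entries of the authors' deposited table passed.

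**Figure D2:**
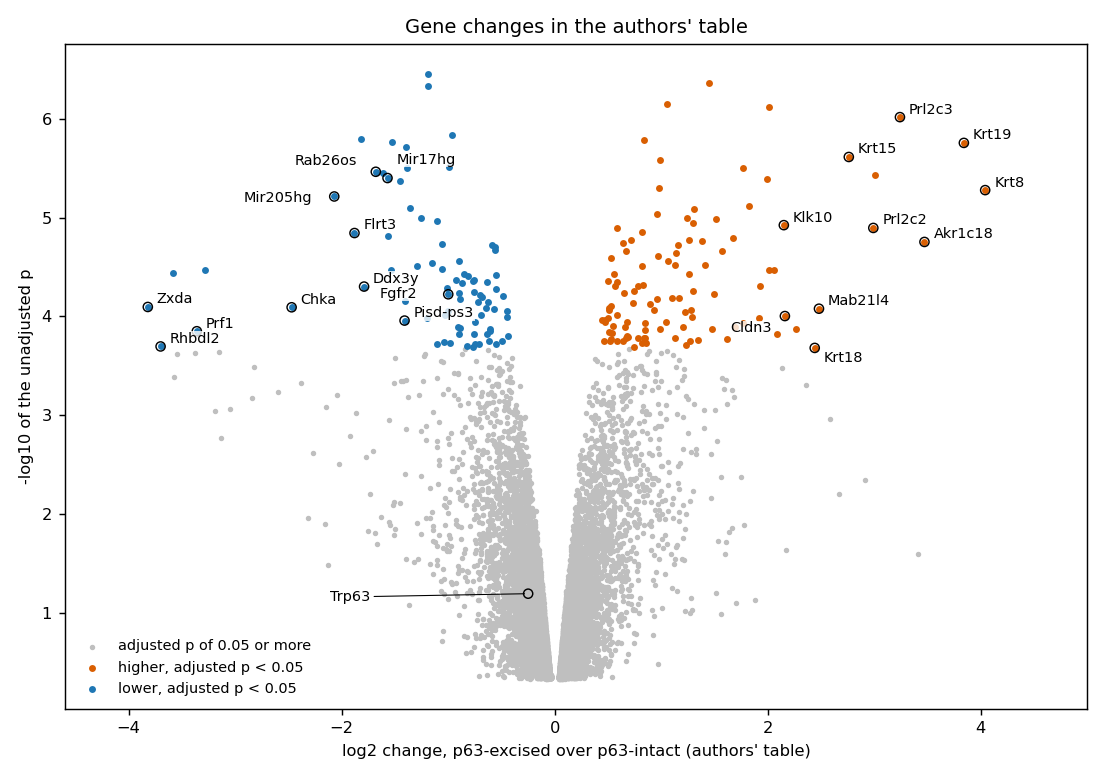
Each point is an entry of the authors' deposited table, with its log2 change, p63-excised over p63-intact, against -log10 of the unadjusted p; orange and blue points passed an adjusted p of 0.05. Krt8 and Krt19 lie farthest right at 4.04 and 3.84, Zxda farthest left at -3.82, and Trp63, circled at -0.25, did not pass.

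Of 29 gene lists tested by the camera procedure on the t values of the authors' deposited table, 4 shifted upward. Among 9 simple epithelial keratins in the authors' deposited table, 7 had positive changes and 3 (Krt8, Krt18 and Krt19) passed over all tests, 5 when adjusted over the list alone (list adjusted p = 2.95e-09). Of 17 genes of desmosomes and other junctions in the authors' deposited table, 11 were positive and 3 rose, 5 when adjusted over the list alone (list adjusted p = 0.00108). Among them were Cldn3 at 2.16 in log2 and Tjp3, a tight junction scaffold gene, at 0.66 in the authors' deposited table. Genes known to be repressed by p63 also shifted upward in the authors' deposited table, with 7 of 10 positive and 2 rising, 3 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.00652). Those 2 were Krt8 and Krt18, which the keratin list also holds, and without them the list gave p = 0.454 in the authors' deposited table. Without the members that passed over all tests, removed because they passed, the junction list gave p = 0.197 in the authors' deposited table. With the inter-gene correlation preset at 0.05 in place of 0.01, all 4 lists still passed in the authors' deposited table (largest adjusted p = 0.0289), but a rank version ended the junction and p63-repressed calls (adjusted p = 0.183 and 0.342). A minimum mean log2 level of 5.5 ended both calls too (adjusted p = 0.434 and 0.104, authors' deposited table), with a mean t of 1.66 against 2.34 for junction genes but 3.46 against 2.54 for p63-repressed genes, of which 7 were left.

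Among 27 genes known to be activated by p63, 17 had negative changes in the authors' deposited table, 1 fell, and when adjusted over the list alone 1 was higher and 6 lower (list adjusted p = 0.0947). The gene that fell, Col17a1, encodes a hemidesmosomal collagen and had a log2 change of -0.77 in the authors' deposited table. Of 20 basal keratinocyte genes in the authors' deposited table, Krt15 rose, Col17a1 fell and 18 did not pass (list adjusted p = 0.899). No member of the list of 41 spinous and granular differentiation genes passed over all tests in the authors' deposited table, where the cornified envelope gene Ivl was at -1.56 and Cdsn at 0.94, with 14 at an unadjusted p under 0.05 (list adjusted p = 0.367). Stress keratins and alarmins in the authors' deposited table had 10 of 13 positive changes and no member past the test, 2 at an unadjusted p under 0.05, with Lcn2 at 2.91 (list adjusted p = 0.574). When adjusted over the list alone, the basal list had 3 genes higher and 2 lower, the differentiation list 2 and 2, and the alarmin list 0 and 1 in the authors' deposited table.

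Among 11 listed FGF receptors and ligands, Fgfr2 fell and 10 did not pass in the authors' deposited table, where Fgfr3 was at -0.58 and the coreceptor gene Sdc1 at 0.43 (list adjusted p = 0.524). None of 15 feedback targets of ERK signalling passed in the authors' deposited table, with 7 at an unadjusted p under 0.05 (list adjusted p = 0.67). The nearest were Etv4, an ETS transcription factor gene, at -0.95 (adjusted p = 0.0692), Epha2, an ephrin receptor gene, at 0.74 (adjusted p = 0.14), and Dusp6, an ERK phosphatase gene, at -0.62 (adjusted p = 0.186) in the authors' deposited table. Adjusted over the list alone, 1 ERK target was higher and 3 were lower, and 1 gene of the FGF list was higher and 1 lower in the authors' deposited table.

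Apoptosis regulators moved both ways in the authors' deposited table: the initiator caspase gene Casp8 rose by 0.98 and the survival gene Bcl2l1 by 0.56, and Casp2 fell by 0.89 (adjusted p = 0.00945, 0.0231 and 0.0292). The other 19 of 22 listed apoptosis genes did not pass in the authors' deposited table, and the list's median log2 change of -0.06 and mean t of 0.43 differ in sign (list adjusted p = 0.574). Of 34 cell cycle genes 26 had negative changes in the authors' deposited table, and none passed, 8 having an unadjusted p under 0.05 (list adjusted p = 0.0947). Rrm2, which had the smallest p of them, was at 0.39, Mki67 at -0.54 and Uhrf1 at -0.61 in the authors' deposited table. Hypoxia and glycolysis genes were negative for 16 of 20 in the authors' deposited table, with Egln3 at -0.82 and the glucose transporter gene Slc2a1 at -0.45, and none passed, 7 having an unadjusted p under 0.05 (list adjusted p = 0.0607). A rank version of the test brought both lists past the threshold (adjusted p = 0.0435 each, authors' deposited table, both downward). None of 21 p53 targets passed in the authors' deposited table, with 7 at an unadjusted p under 0.05, among them Ercc5 at -0.35, Epha2 at 0.74, Phlda3 at -0.66 and Pmaip1 at 0.33 (list adjusted p = 0.517). None of 14 genes of the epithelial-mesenchymal transition passed in the authors' deposited table, 5 having an unadjusted p under 0.05, with Snai2 at -1.26 and Tgfbi at -0.80 (list adjusted p = 0.377). Notch pathway genes gave no member past the test among 14 in the authors' deposited table, 3 at an unadjusted p under 0.05, with Notch3 at 0.36 and Notch4 at -0.43 (list adjusted p = 0.837). Interferon-stimulated genes were positive for 20 of 24 in the authors' deposited table, none passing and 4 at an unadjusted p under 0.05, with Irf7 at 0.69 and Ifi35 at 0.68 (list adjusted p = 0.136). Adjusted over the list alone, 3 apoptosis genes were higher and 2 lower, 1 p53 target was higher and 1 lower, 2 genes of the mesenchymal transition were lower, and the cell cycle, hypoxia, Notch and interferon lists had 0 calls in the authors' deposited table.

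Because every p63-excised tumour also received tamoxifen, which binds the estrogen receptor, lists for drug responses were examined. Wnt4, an estrogen-responsive ligand gene, rose by 1.29 in the authors' deposited table (adjusted p = 0.0362), and the other 9 of 10 estrogen-responsive genes did not pass. Of these 10 genes 7 had positive changes and 3 an unadjusted p under 0.05 in the authors' deposited table (list adjusted p = 0.171). Esr1, Pgr and Greb1 had mean log2 levels of 4.82, 4.87 and 4.85 in the authors' deposited table. These lie near the lowest listed level of 4.62, where a fall could hardly be seen. In that list Ltf, encoding lactoferrin, was at 3.41 (p = 0.0253), Ccnd1 at 0.51 (p = 0.058) and Areg at -1.05 (p = 0.0362) in the authors' deposited table. Of 15 cholesterol synthesis genes in the authors' deposited table only Ebp, encoding a sterol isomerase, passed, with a rise of 0.68 (adjusted p = 0.045), and 14 did not (list adjusted p = 0.377). None of 12 dissociation and stress early genes passed in the authors' deposited table, 4 having an unadjusted p under 0.05, with Jund at a fold of 2.83 and Hsph1 at a log2 change of -0.75. The median of the stress genes, -0.08, and their mean t, 0.10, differ in sign in the authors' deposited table (list adjusted p = 0.899). Adjusted over the list alone, 1 estrogen-responsive gene was higher, 2 cholesterol genes were higher and 1 lower, and 1 stress gene was higher in the authors' deposited table.

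Skeletal muscle genes shifted upward as a list in the authors' deposited table, with 28 of 29 positive (list adjusted p = 0.00016). No muscle gene passed over all tests in the authors' deposited table, 9 had an unadjusted p under 0.05, and 3 rose when adjusted over the list alone: Des, the muscle intermediate filament gene, by 1.40, Cox6a2 by 0.75 and Pgam2 by 0.43. Atp2a1, the calcium pump gene of fast muscle, was at 1.47 in the authors' deposited table and did not pass over all tests (adjusted p = 0.293). Genes of 1 tissue vary together, and a correlation estimated from the arrays was not analysed here; at a preset 0.05 the muscle list had an adjusted p of 0.0186 in the authors' deposited table. Limited to entries with a mean log2 level of at least 5.5, the muscle list held 8 genes in the authors' deposited table, all positive with a median of 1.33 against 0.26 for all 29. The level is a mean over both groups, so genes low in intact tumours pass only through their rise, and the larger median is partly built in. The muscle list then missed the threshold (adjusted p = 0.249), with fewer members and a wider spread of t over entries of the authors' deposited table (SD over entries 3.41 against 2.32). Without Des the full muscle list gave p = 4.5e-05 in the authors' deposited table.

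Other host cell types gave no list past the threshold in the authors' deposited table. Of 15 fibroblast and matrix genes, Fbln1 fell by 0.82 in the authors' deposited table (adjusted p = 0.0482) and 14 did not pass, with a list median of -0.29 (list adjusted p = 0.377). Macrophage and monocyte genes had a median of -0.31 over 18 genes in the authors' deposited table, with the lysozyme gene Lyz2 at -1.73, none passing and 3 at an unadjusted p under 0.05 (list adjusted p = 0.377). Endothelium and pericyte genes had a median of -0.23 over 14 genes in the authors' deposited table, with Esam at -0.67 and Robo4 at -0.28, none passing and 6 at an unadjusted p under 0.05 (list adjusted p = 0.289). Red blood cell genes were negative for 8 of 9 in the authors' deposited table, with the globin genes Hbb-b1 at -2.32 and Hba-a1 at -2.13, none passing and 2 at an unadjusted p under 0.05 (list adjusted p = 0.171). Of 14 lymphoid and mast cell genes in the authors' deposited table, Prf1 fell and 13 did not pass (list adjusted p = 0.377). The list's median log2 level was 4.9, near the lowest listed level of 4.62, against 6.88 for Prf1. The fall of Prf1 therefore does not show a loss of lymphocytes. Neutrophil genes had a median of -0.07 and a mean t of 0.17, which differ in sign, over 15 genes in the authors' deposited table, none passing and 2 at an unadjusted p under 0.05 (list adjusted p = 0.859). No member passed among adipocyte and sebocyte, hair follicle and melanocyte, or nerve and Schwann genes in the authors' deposited table, where 1, 4 and 1 had an unadjusted p under 0.05 (list adjusted p = 0.837, 0.71 and 0.517). Of 4 listed sex-linked genes, too few for a list test, Ddx3y fell and Tsix, Kdm5d and Usp9y did not pass in the authors' deposited table. Adjusted over the list alone, the fibroblast, lymphoid and sex-linked lists had 1 lower gene each and the other lists of this paragraph 0 in the authors' deposited table.

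**Figure D3:**
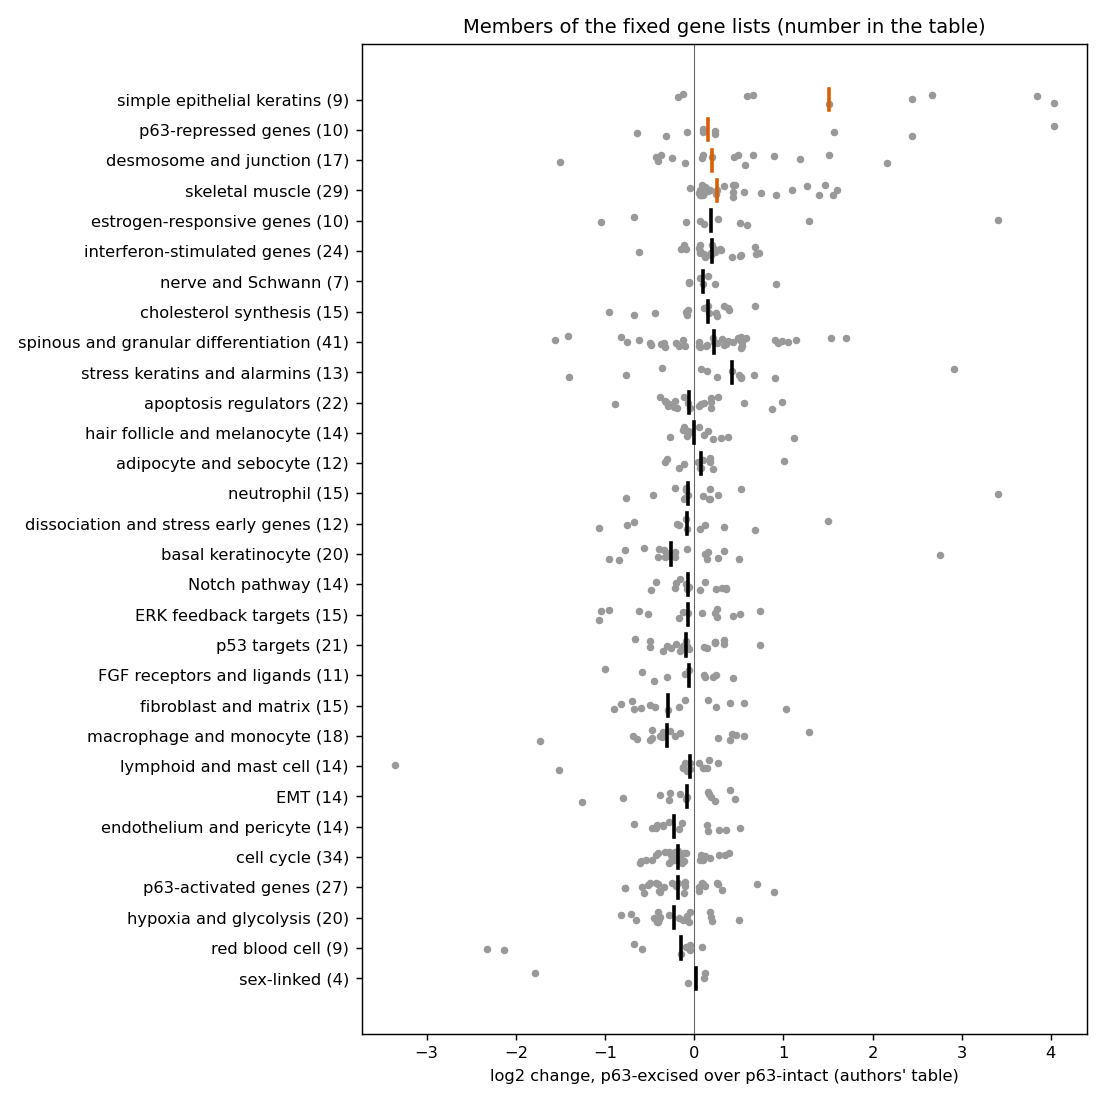
Log2 changes, p63-excised over p63-intact, of the members of each fixed gene list in the authors' deposited table; each grey point is a gene, the bar is the list's median, and the number listed stands in parentheses. Orange bars mark the 4 lists past an adjusted p of 0.05, among which the simple epithelial keratins have a median of 1.51 and skeletal muscle 0.26.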

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

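The alternatives for gene counts and lists were chosen after seeing the data; those for probes were planned. The 604 probes became 396 with normexp at an offset of 50, 298 without background correction, 380 in the authors' value table, 203 with no filter on dim probes (45281 tested), 963 with array weights and 50 with median scaling. All 50 probes called with median scaling were among the 604, and the cause of these differences was not tested. Requiring detection on all 6 arrays gave 433 and a variance trend with robust estimation 616. Leaving out 1 array gave 186 to 631 probes: 301, 224 and 186 without p63-intact 1, 2 and 3, 328 and 233 without p63-excised 1 and 3, and 631 without p63-excised 2, of which 471 were among the 604. With the replicate number as a block 1324 probes passed, including all 604. Deviations of same-numbered arrays correlated at 0.34, 0.38 and -0.06, and those of differently numbered arrays at -0.37 to 0.14. The pairs of number 1 and of number 2 were the highest, but p63-intact 3 correlated best with p63-excised 2 (0.11). With 3 arrays per group, these values cannot decide whether equal numbers mark a pair or a batch. In the authors' deposited table, 190 entries passed over 45281 tests, 253 over an estimated 32023 and 486 over the 16381 listed, where fewer tests are the cause by construction. The 4 lists past the threshold in the authors' deposited table became 1 among entries with a mean level of at least 5.5, the simple epithelial keratins, where the p63-repressed, junction and muscle lists had adjusted p of 0.104, 0.434 and 0.249. Their median log2 changes in the authors' deposited table went from 0.16, 0.20 and 0.26 to 0.23, 0.09 and 1.33, with 7, 11 and 8 members left and a wider spread of t over entries (SD 3.41 against 2.32). Genes low in intact tumours pass this filter only through a rise, so the muscle median of 1.33 is partly built in. The lists past the threshold numbered 4 at a correlation of 0.05 and 4 with ranks, of which 2 were among the first 4, and 5 with unlisted members at a t of 0, where hypoxia was added (adjusted p = 0.0294, authors' deposited table). Direction turned, without a call, for basal keratinocyte (adjusted p = 0.953) and Notch genes (0.876) in the dim filter, and for apoptosis and dissociation genes (0.963 each) with ranks, in the authors' deposited table; the cause was not tested. Of the single lists, 29 of 29 at the correlation of 0.05, 28 of 29 with unlisted members at 0, 23 of 29 with ranks and 17 of 22 with the dim filter kept direction and side. Not run were other settings for Trp63, Fgfr2, named genes and lists, including an estimated correlation, fry and leaving out arrays, and one probe per gene, all of which need named probes, and the slide as a block, since no slide is used here. Low signal over background on p63-excised 2 (upper-percentile signal over median 5.36, against 9.31 to 15.12 on the other arrays) limits what is detected there.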

Other observations

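Several genes outside the lists and the naming rule are given here, chosen after their values were seen. Rises in the authors' deposited table included Wfdc2 by 1.82 in log2, Chil1 by 1.77, Padi1 by 1.93, Plac1 by 2.01 and Msln, encoding mesothelin, by 1.62 (adjusted p = 0.0126, 0.00833, 0.0259, 0.0224 and 0.0458). Elf3, an epithelial ETS factor gene, rose by 1.92, the sodium channel gene Scnn1a by 1.24, the membrane protease gene St14 by 0.96 and its target receptor gene F2rl1 by 0.97 in the authors' deposited table (adjusted p = 0.0362, 0.0143, 0.014 and 0.0196). Of 19 listed kallikrein genes 16 had positive changes in the authors' deposited table and Klk10 and Klk9 rose, Klk9 by 1.99 and 2.06 in its 2 entries (adjusted p = 0.00837 and 0.0224). Wnt ligand genes moved both ways in the authors' deposited table, with Wnt4 and Wnt7b higher by 1.29 and 1.57 and Wnt3a lower, at -1.26 (adjusted p = 0.0362, 0.0181 and 0.0143).

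All 7 listed small nucleolar RNA host genes had negative changes in the authors' deposited table, and Zfas1 and Snhg17 fell, by 1.03 and 0.90 (adjusted p = 0.0351 and 0.021). Among 45 listed ribosomal protein genes 33 were negative in the authors' deposited table, with a median of -0.22, and only Rpl23 fell. These families were also chosen after their values were seen and were not tested as lists.

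The 3 patterns below were picked after viewing the values, from several looked over that also included sex-linked, tamoxifen-responsive and ribosomal genes. Both muscle tests and the test of background noise were chosen after their results were seen; the other tests were set after the pattern but before their own results. For the 604 probes, 1 of the 10 splits of the 6 arrays, the real one, gave as many, and the highest of the others gave 0; 10 splits are too few for a share under 0.05.

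The muscle list shifted upward in the authors' deposited table, with 28 of 29 genes positive but 0 past the threshold over all tests. More host muscle in those samples stays open, since that count restates the shift. A lower share of tumour cells would raise the other host types alike. Among entries with a mean level of at least 5.5, the 53 genes of the 9 other host cell type lists had a median of -0.35 in the authors' deposited table, 31 being negative. The 90th percentile of those genes, 0.85, lay below the muscle median of 1.33 at that level in the authors' deposited table. But the level is a mean over both groups, so muscle genes low in intact tumours pass only through their rise. Over all 29 muscle genes the median was 0.26, below that percentile. The comparison therefore cannot decide on a lower share of tumour cells, which stays open. The p63 excision itself was not tested as a cause.

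Clone-named or noncoding transcripts made up 38 of 82 falls (46.3%) but 11 of 108 rises (10.2%) in the authors' deposited table (Fisher's exact test, p = 3.01e-08), against 31.2% of all listed entries. The contrast was picked after these calls were seen, and the test takes entries of the same 6 arrays as independent. That p-value is therefore descriptive only. Background noise stays open: 100% of the 38 clone-named or noncoding falls had a mean level above the median listed entry in the authors' deposited table. But so had 100% of the 141 called entries that are neither clone-named nor noncoding, so being called sets that share. The low signal over background of array p63-excised 2 stays open too, since the 309 probes called lower without that array are unnamed. A shared loss of nuclear and unstable RNA, from RNA handling or from the tumours, stays open. A list of nuclear-retained and splicing-regulator transcripts was written after these falls were seen, and genes noted as already seen were left out. Snhg12, of the small nucleolar RNA host family above, stayed in, and whether its value had been seen by then is not known. The 20 listed members of that list had a median of -0.36 in the authors' deposited table, 18 being negative (camera p = 8.68e-07, and 0.000121 at a correlation of 0.05), as such a loss would predict. But they include mRNAs of splicing factors such as Srsf6, Tra2a and Rbm5. A fall of these shows neither a loss of nuclear RNA nor why clone-named transcripts fell.

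Among probes, 14 fell by over 3 on the log2 scale, with a median of -3.63. Their deviations from the group means correlated at 0.791 on average, above the 95th percentile of 0.281 among 1000 random sets matched on level and spread, none of which reached it, so these probes may read 1 shared transcript or repeat family. The median was still -3.21 in the weakest case when each array was left out. But the probes were chosen on the same arrays for a fall over 3 past an adjusted p of 0.05, which favours falls shared by arrays. That median was therefore largely set by the choice and does not show that such falls would recur in other tumours. For these 14 probes as a set, medians of -3.21 to -4.02 without each array argue against a single array as the source. A coordinated loss of separate transcripts after p63 excision was not tested and stays open, since these probes are unnamed here.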
